A study of Rattus norvegicus with 6 samples.

How the data were processed

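Total RNA from rat soleus muscle was profiled on expression arrays in 6 samples, each labelled as taken after 14 days of hindlimb suspension. Per the labels' protocols, the RNA was isolated from cryosections with the RNeasy kit and 5 µg of total RNA was used per array. The array platform, the scanner, the background method and the probe sequences are not given in the sources used here. The deposited values are intensities, 1 per feature and sample, for 1185 features. They are whole numbers that reach below 0 in every sample, as background-subtracted intensities do. Their medians differ between samples, so the deposited intensities had not been set to a common median. Whether the authors scaled them in another way is not given in the sources used here. No detection calls were used here, and the number of arrays and the distance of each signal from background limit the precision.

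The features carry identifiers of 2 series, R followed by a number and RG followed by a number. None of them (0 of 1185) matched a gene identifier, symbol, synonym or accession in the rat RefSeq gene table of the GRCr8 assembly. The 20 gene lists fixed for muscle, metabolism and other cell types before the data were examined, with 636 entries, could therefore not be evaluated, and no result is given for any of them. No genomic positions are given for the same reason.

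All 6 samples belong to 1 group. Loaded control muscle was not analysed here, so no test between conditions was made. The labels do not say whether the 6 samples came from separate animals, and the spread between them may be partly technical. Replicates were numbered 1 to 6 in accession order, and these numbers only name the samples. No sample was left out of the main results, and no 2 samples shared more than 2 identical values.

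A feature was called measured where its intensity was above 0 in all 6 samples. Intensities of these features were put on the log2 scale with no pseudocount, and each array was centred on its median over the measured features. The spread of a feature was the SD of these values over the 6 samples. Agreement was Pearson's r across features for each of the 15 pairs of samples; features are not independent replicates, so no p-value is attached. The relative SD of a feature was its SD divided by the median SD of the 101 features nearest to it in mean level. The noise of each array near background was summarised by a robust SD, 1.4826 times the median size of its values below 0. Because no gene names could be attached, the rule fixed before the data were examined allowed the 2 features with the highest and the 2 with the lowest relative SD to be named. Brightness depends on the probe as well as on the transcript, so levels of different features are not ratios of transcript abundance.

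The relative SD procedure was tested on simulated data of 625 features with the observed means and normal noise on the log2 scale. The SD of each feature was the median SD of features of like level (median 0.615, against 0.669 observed). With the SD of 60 features raised 2-fold or 3-fold, all 10 of the highest-ranked features were raised ones in each simulation. The simulation did not model background noise of intensities close to 0, so it does not show how the ranking behaves there. For deviations from the feature means, the correlation expected of independent samples was computed from the variance of each sample, and its bootstrap SD from 200 resamplings of the features. Alternatives were quantile normalization, no centring, 2 filters on dim features, a pseudocount of 191 (the 10th percentile of the intensities above 0, with values below 0 set to 0), rank correlation, the linear scale and leaving out each sample in turn. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.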

Results

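Gene expression was measured in the soleus, a postural muscle of the lower leg, of young female Wistar rats after 14 days of hindlimb suspension. In this treatment the hind feet are kept off the ground, so that the muscle no longer carries the animal's weight. The data set held 1 group of 6 samples and 1185 array features, of which 702 had identifiers beginning with R and 483 identifiers beginning with RG. The design contains no contrast between conditions. The quantities that can be derived are therefore which features gave signal in the suspended muscle, how reproducible each level was, and which features differed most between samples.

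Most features had an intensity above 0 in each sample, but fewer stood clear of background noise. Of the 1185 features, 938.8 ± 53.2 (SD, n = 6) had an intensity above 0, a share of 79.2% ± 4.5 (SD, n = 6). The number ranged from 838 in replicate 5 to 980 in replicate 1. In all 6 samples together 625 features (52.7%) were above 0, 524 features were above 0 in 1 to 5 samples, and 36 features were at or below 0 in every sample. Among the R features 395 of 702 (56.3%) were measured in all 6 samples, and among the RG features 230 of 483 (47.6%). The median intensity over all features was 936 ± 245 (SD, n = 6), with the lowest median, 484, in replicate 5. The medians of the other 5 samples averaged 1027 ± 117 (SD, n = 5). The robust SD of the values below 0 was 543 ± 63.5 intensity units (SD, n = 6), so that an intensity of about 1630, the mean of 3 robust SDs, stood clear of background in a typical array. By that stricter criterion, added after the data were seen, 472 ± 60.8 features (SD, n = 6) stood clear of background in a sample, from 386 (32.6%) in replicate 5 to 566 (47.8%) in replicate 6. In all 6 samples 307 features did so.

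A small set of features carried much of the signal. The 10 features with the highest mean intensity held 50.6% ± 6.6 (SD, n = 6) of the summed intensity above 0, from 42.2% in replicate 5 to 60.3% in replicate 2. The brightest feature had a mean intensity of 2068335 ± 1668734 (SD, n = 6). It lay between 1973593 and 4584577 in replicates 1 to 4, but at 315832 in replicate 5 and 219594 in replicate 6. The second brightest feature showed the same division, with 1241671 to 1757573 in replicates 1 to 4 against 396518 in replicate 5 and 355198 in replicate 6. The third had intensities of 1326816, 1220952 and 3369027 in replicates 3, 4 and 6, and of 149785 to 174673 in the other samples. By contrast, the fifth brightest feature had intensities of 589338 to 895225, with a mean of 741017 ± 117288 (SD, n = 6). After the array medians were equalised it varied 2.65-fold between the highest and lowest sample. The seventh and eighth brightest then varied 2.44-fold and 2.58-fold. The total intensity ranged from 11628758 in replicate 5 to 16209837 in replicate 2.

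The spread between samples set the error of each level. The median SD over the 625 measured features was 0.67 on the log2 scale (n = 6 samples per feature), with an interquartile range of 0.49 to 0.996. This corresponds to a median coefficient of variation of 43.7% and a median standard error of the mean of 0.27 on the log2 scale. The median feature differed 3.41-fold between its highest and lowest sample. All 6 samples lay within 2-fold of each other for 78 features (12.5%), whereas 84 features (13.4%) varied more than 10-fold. Many of these folds were taken against intensities not clear of background: of the 307 features above 3 robust SDs in all 6 samples, 14 (4.56%) varied more than 10-fold, and their median SD was 0.55. The spread was highest among dim features. In the dimmest quartile, with a median intensity of 887, which is not clear of background, the median SD was 1.03 and 47 of 157 features varied more than 10-fold. In the second quartile the median SD was 0.70 and 16 of 156 features varied more than 10-fold, and in the third it was 0.57 and 8 of 156 did so. In the brightest quartile, with a median intensity of 23269, the median SD was 0.58 and 13 of 156 features varied more than 10-fold.

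**Figure D1:**
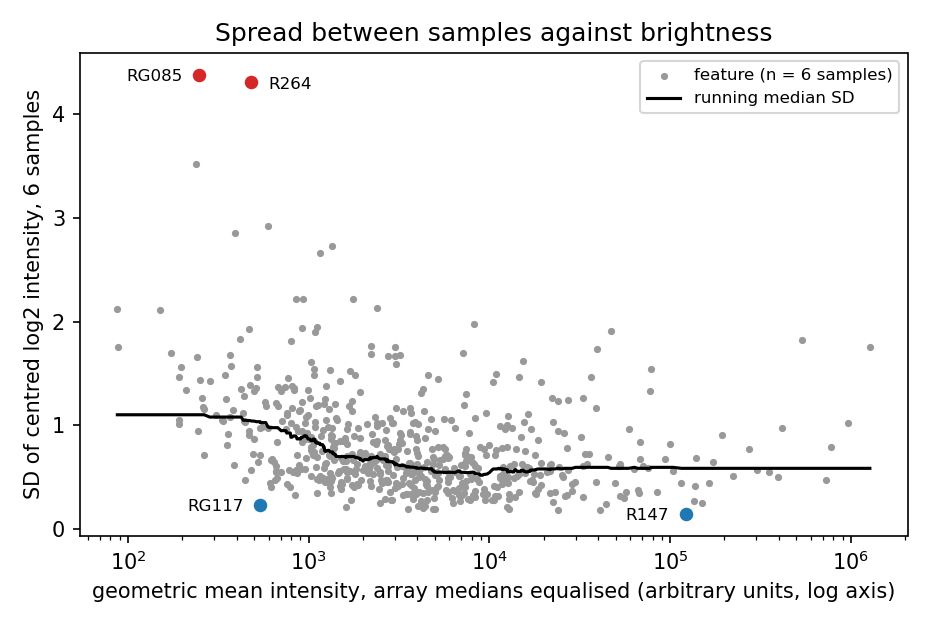
SD of the centred log2 intensity over 6 samples (vertical axis) against the geometric mean intensity with array medians equalised (horizontal log axis, arbitrary units) for each of 625 measured features (grey points), with the running median SD of features of like level (black line). The features with the 2 highest (red) and 2 lowest (blue) SDs relative to that line are labelled, and the median SD is 1.03 in the dimmest quartile, 0.57 in the third and 0.58 in the brightest.

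The expression profiles of the 6 samples resembled each other, with replicates 5 and 6 farthest from the rest. On the log2 scale over all measured features replicate 5 agreed least, whereas over bright features and on the linear scale replicate 6 did. The median of the 15 pairwise correlations across features was 0.873. Within single quartiles of brightness it was 0.30 in the dimmest, 0.11 in the second, 0.19 in the third and 0.82 in the brightest. Much of the value of 0.873 therefore reflects the wide range of brightness between features. Over all measured features the highest correlations were 0.932 between replicates 3 and 4 and 0.918 between replicates 1 and 2. The lowest was 0.751 between replicates 5 and 6. The median correlation of a sample with the other 5 was 0.801 for replicate 5, against 0.840 to 0.897 for the other samples. Replicate 5 was the highest or the lowest of the 6 samples for 61.1% of features and replicate 6 for 41.6%, where equal samples would each give 33.3%. The remaining 4 samples had shares of 22.9% to 26.1%. In the brightest quartile these shares depended on the centring. They were 67.9% for replicate 5 and 51.9% for replicate 6 there, but 44.2% and 62.8% after centring within that quartile. In the dimmer quartiles, centred in the same way, replicate 5 kept the highest share, 56.7% to 63.5%. Replicate 4, whose title has another form than those of the other samples, had a median correlation of 0.880 with them and did not stand apart. On the linear scale, where the brightest features dominate, the median pairwise correlation was 0.627, with 0.981 between replicates 1 and 2, 0.965 between replicates 3 and 4 and 0.192 between replicates 2 and 6. The median correlation with the other samples was then 0.379 for replicate 6 and 0.609 for replicate 5, against 0.863 to 0.897 for replicates 1 to 4. Over the brightest quartile on the log2 scale it was 0.731 for replicate 6, 0.762 for replicate 5 and 0.891 to 0.900 for replicates 1 to 4.

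**Figure D2:**
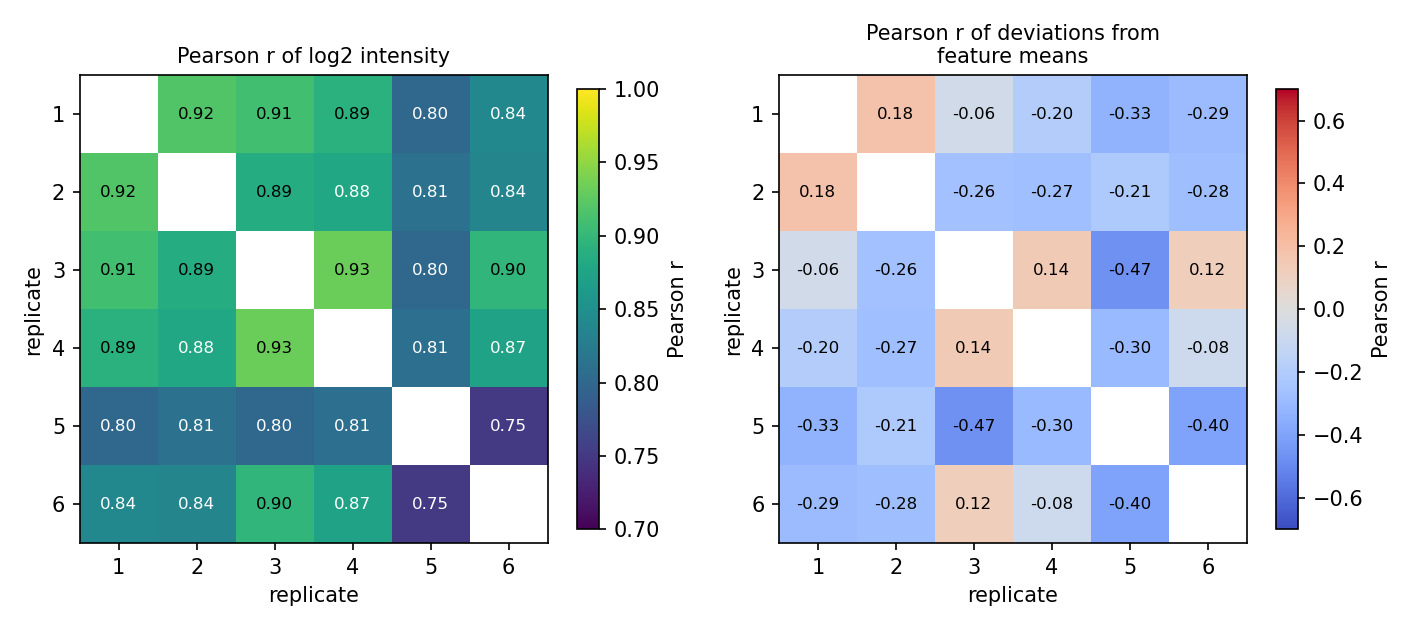
Pearson correlation across 625 measured features for each pair of the 6 samples, for centred log2 intensities (left) and for their deviations from each feature's mean (right); both axes give the replicate and the colour scale gives r. Replicate 5 has the lowest correlations on the left, down to 0.751 with replicate 6, and replicates 1 and 2 have the highest value on the right, 0.18.

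Relative to features of like brightness, the most variable were R264 and RG085. The pair kept the top 2 ranks in 2 of 11 alternative settings, and neither was among the top 2 in 5 of them, of which 1, the filter on dim features, had removed both. R264 had an SD of 4.31 on the log2 scale, 4.13 times the SD of features of like level. Its intensity was 5654 in replicate 3 and 4973 in replicate 6, 653 to 891 in replicates 1, 2 and 4, and 1 in replicate 5, so that only replicates 3 and 6 lay above 3 robust SDs of their background. RG085 had an SD of 4.38, 3.97 times that of features of like level. It had an intensity of 19812 in replicate 5 and of 3 to 815 in the other 5 samples, which all lay below 3 robust SDs of their background. For both features the size of the SD rests partly on intensities close to 0, where the log scale stretches small differences. Without replicate 5 the relative SD of R264 was 2.68 and that of RG085 was 2.69. With a pseudocount of 191 added to all features, the relative SD of R264 was 2.05 and that of RG085 was 3.32. The 10 most variable features had relative SDs of 3.11 to 4.13. Their lowest sample was replicate 5 for 4 of the 10, replicate 1 for 3, replicate 4 for 2 and replicate 6 for 1. Only 4 of these 10 were also among the 10 most variable when replicate 5 was left out.

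The lowest relative SDs were those of RG117 and R147. Both were picked as the lowest of 625 features with 6 samples each, and such a pick yields low SDs by itself. The simulation only raised SDs, so whether these features were steadier than others of like level was not tested. R147 had an intensity of 122596 ± 12403 (SD, n = 6) and ranged from 101243 to 137545, with an SD of 0.15 on the log2 scale and a coefficient of variation of 10.8% after the array medians were equalised. RG117 had an intensity of 555 ± 137 (SD, n = 6), below 3 robust SDs of background in every sample, with an SD of 0.24 on the log2 scale. Their SDs were 0.25 (R147) and 0.23 (RG117) times those of features of like level, and 0.43 and 0.41 times after quantile normalization. Over features above 0 in at least 4 samples the ratio of R147 was 0.056, and the ratio of RG117 was 0.36 with no centring and 0.34 without replicate 5. The 10 least variable features had SDs of 0.15 to 0.24 and a highest-to-lowest ratio of 1.33 to 1.53. None of the 10 was among the 10 brightest features, whereas 1 of the 10 most variable was.

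**Figure D3:**
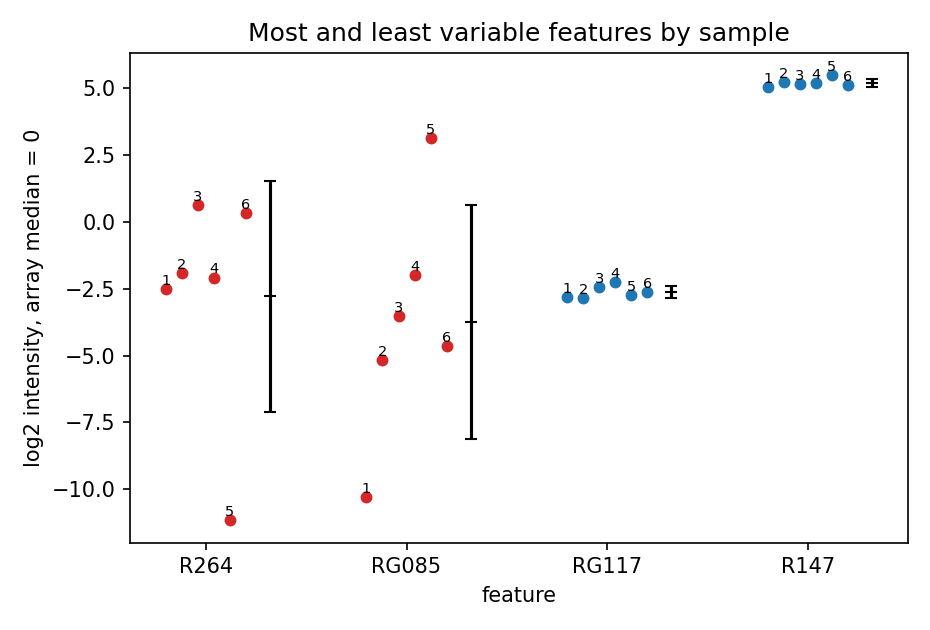
Centred log2 intensity (vertical axis, array median at 0) of the 2 most variable features, R264 and RG085 (red), and the 2 least variable, RG117 and R147 (blue), in each sample; digits give the replicate and the bars beside the points give the mean and SD over 6 samples. The spread of R264 is set largely by replicate 5, at -11.16, and that of RG085 by replicate 5 at 3.12 and replicate 1 at -10.29.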

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

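A gap test for a single outlying sample (Dixon's, which flags about 1 in 20 groups by chance) was applied to 25 quantities and flagged 3. One of them, R264, had been picked from these same data as the most variable feature, so that rate does not apply to it. The tests of explanations in this part were chosen after the values were seen. R264 stood at -11.16 on the centred log2 scale in replicate 5, against -2.52 to 0.63 in the other samples. That value is the logarithm of an intensity of 1, and the intensities of 653 to 891 in replicates 1, 2 and 4 also lie below 3 robust SDs of their background (1655 to 1790), so the gap between them is of the order of the noise near 0, stretched by the log scale. The third brightest feature had an intensity of 3369027 in replicate 6, against 149785 to 1326816 in the others. It was tested on the linear scale, unlike R264. Replicates 3 and 4, at 1326816 and 1220952, also lay far above the 149785 to 174673 of replicates 1, 2 and 5. Replicate 6 was therefore not the only high sample for this feature. The robust SD of the values below 0 was 417 in replicate 6, against 552 to 597 in the others. Applied to each of the 625 measured features, the same test flagged 92 (14.7%), and replicate 5 was the outlying sample in 53 of them. It was the lowest sample in 40 of these 53 and the highest in 13. Because the log scale stretches intensities close to 0 downwards, the rate of 1 in 20 need not hold for these features.

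Replicate 5 agreed least with the other samples, with a median correlation of 0.801. An additive offset as the whole cause is argued against: adding 242 intensity units, which brings its lower quartile to the mean of the others, gave a median correlation of 0.816, still below the lowest of the others (0.847) by more than their SD (0.019). Noise of dim features as the reason that replicate 5 ranked below replicate 6 stays open. Over the brightest quartile the order was reversed, with 0.762 for replicate 5 and 0.731 for replicate 6. In the third quartile, with a median intensity of 5240, the median absolute deviation of replicate 5 was 0.62. It was 0.28 to 0.41 in the other samples there, so the larger deviations of replicate 5 were not confined to the dimmest features. By median correlation, however, replicate 5 was not the lowest sample in the third quartile, at 0.039 against 0.026 for the lowest other sample. It was the lowest in the dimmest quartile (-0.063 against 0.21) and in the second (-0.16 against 0.012). Its distance from replicates 1 to 4 is not accounted for by such noise: over the 220 features with a mean above 10 robust SDs of background its median correlation was 0.778, against 0.887 to 0.899 for those 4 samples, and that of replicate 6 was 0.739. A weaker or differently processed array and a difference between animals stay open for replicate 5, since the labels give neither a batch nor an animal and no biological explanation was tested.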

How the results depend on the processing

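The median SD was 0.67 in the main setting. It was 0.56 without replicate 5, 0.77 over features above 0 in at least 4 samples, and 0.55 over the 307 features above 3 robust SDs. Every change was below 0.155, the SD over the 6 samples of their median absolute deviation, but replicate 5 itself widens that limit. Without replicate 5 it would be 0.077. These 3 alternatives, and leaving out the dimmest quartile (0.59), each moved the median SD by more than 0.077. The number of measured features was 921 for at least 4 of 6 samples, 451 above the 25th percentile of the values above 0 (527 intensity units), and 307 above 3 robust SDs, the last added after the data were seen. It was 637 to 723 with 1 sample left out, the highest without replicate 5. The median pairwise correlation was 0.833 to 0.879 with 1 sample left out, 0.867 by Spearman's method and 0.627 on the linear scale. The identity of the most and least variable features changed with the setting. Of the 10 highest, 6 were shared with quantile normalization, 6 without the dimmest quartile, 7 with no centring, 7 over features above 0 in at least 4 samples and 3 with the pseudocount of 191. With 1 sample left out, 4 to 9 were shared, the lowest without replicate 5. Of the 10 least variable features, 2 to 7 were shared, fewer than of the 10 most variable in 10 of the 11 alternatives. The dim-feature filter removed R264, RG085 and RG117 from the ranking, which shows why they could not be ranked there; otherwise the cause was not tested. The alternatives foreseen for the gene lists were not run, because no identifier could be paired with a gene. No paired analysis was possible because the labels give 1 group.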

Other observations

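The tests in this part were chosen after the values were seen, except the test of the strongest positive correlation, whose expected outcome was written before it was run. Values far below background were not scattered at random. In 33 features at least 1 sample lay more than 10 robust SDs below 0, with 9 to 17 such values per sample and a lowest intensity of -84923. In 23 of these features another sample was above 0. Every one of the 15 pairs of samples shared more of them, 2 to 10, than the 0.068 to 0.23 that independent samples would share. The highest numbers were 10 for replicates 1 and 2 and 10 for replicates 3 and 4, followed by 7 for replicates 1 and 3, 2 and 3, and 2 and 4.

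A candidate explanation is that signal of very bright features was counted as background of other features. Across the 6 samples, the mean strongest negative correlation of the 33 features with any of the 5 brightest features was -0.735, against a median of -0.543 over all 720 pairings of the samples (exact permutation test, one-sided p = 0.0028, unadjusted). With the 10 brightest features p was 0.0042. A grouping of the samples shared by all features would also raise the strongest positive correlation, which was 0.555 against a median of 0.499 (exact permutation test, one-sided p = 0.21), so it stays open. The positions of the features on the array, which would decide whether the bright and the negative features were neighbours, were not used here.

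Replicates 1 and 2 deviated from the feature means together. The correlation of their deviations was 0.18, where independent samples of the same variances would give -0.09. This was the highest of the 15 pairs, so the pair stands out by selection from these same data. Over all measured features its excess was 0.275 (bootstrap SD 0.069), close to the 0.266 of replicates 3 and 6. The values argue against each of 3 sources, taken alone as the whole cause for this pair. Over the brightest quartile (noise of dim features) the correlation was 0.54 against 0.011. Without the features in the top 25% by relative SD (a few very variable features) it was 0.25 against -0.060. With replicate 5 left out (its distance from the rest) it was 0.13 against -0.26. Each was a larger departure than that of any other pair, but the features used overlap those that picked the pair. The sources were not removed together, so a combination of them stays open. For replicates 3 and 4 (0.14 against -0.0043 over all measured features) these sources stay open. In the same order the values were 0.19 against 0.037, -0.051 against -0.099 and -0.0040 against -0.13. The excesses were 0.149, 0.048 and 0.125, with bootstrap SDs of 0.125, 0.058 and 0.053. Without the very variable features the excess was thus within its bootstrap SD, the outcome predicted if they were the source. In all 3 settings other pairs departed by more. Replicates 3 and 6, at 0.12 against -0.15 over all measured features, were one of them. An unlabelled array batch or a relation between animals was not tested, and both stay open.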
